A study of Bos taurus with 20 samples.

How the data were processed

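Muscle from the anterior limb of 20 male beef cattle was profiled on Agilent bovine oligonucleotide arrays with a single dye (Cyanine 3), with 1 array per animal. Per the labels, 9 animals were untreated, 5 received dexamethasone and 6 received dexamethasone together with estradiol. The animal codes in the labels are of 2 kinds among the controls: control replicates 1 to 3 carry codes with an M and control replicates 4 to 9 carry codes with a K. Code numbers form 1 run: D2 to D6 under dexamethasone, K7 to K12 in the K controls and DE13 to DE18 under dexamethasone plus estradiol. The M codes have another form and are not part of this run. What the codes stand for is not given in the sources used here. Whether the K controls and the treated animals were kept as 1 trial is therefore not known. Replicate numbers only name animals within a group, in the order of deposit.

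The deposited values are intensities on a linear scale. Per the series' design text, each slide was scanned at 2 sensitivity settings, and the authors extracted a background-subtracted and detrended signal with the Agilent extraction software. The deposited intensity columns share the same minimum (5.2), median (198.53) and maximum (491564.94) on all 20 arrays, so values had been equalised between arrays before deposit. The method of that step, and the rule by which spots were left without a value, are not given in the sources used here. Of 44407 spots, 30340 (control replicate 6) to 41306 (dexamethasone plus estradiol replicate 1) had a value. Missing values were mostly dim: 34.4% of cells were empty in rows with a mean log2 intensity under 4, and 0.36% in rows with a mean of 10 or more. Because equal quantiles were imposed over unequal numbers of spots, the median log2 intensity of the 20595 spots with a value on all arrays ranged from 9.48 (control replicate 6) to 10.57 (dexamethasone plus estradiol replicate 1). Depth in the sense of read counts does not apply to arrays; the number of arrays per group limits the precision.

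Intensities were converted to log2. The upper quartiles of the arrays were already equal, so the planned subtraction of an upper quartile had no effect. Gene names came from the array annotation, updated through the NCBI RefSeq gene table of assembly ARS-UCD2.0, which served for names only; no coordinates were used. The annotation gave 1 gene symbol to 6954 rows (3287 accessions) and none to 37453 rows, which stayed in the tests as unnamed features; control spots among them could not be separated. Of the accessions, 2563 were matched by accession, 366 by gene identifier, 280 by symbol and 77 by synonym, and 1 kept its name as given. Of the 3287 accessions, 3133 had 2 rows. Repeats among the unnamed rows could not be recognised, so each unnamed row was its own feature. Counts of features can therefore hold 1 probe more than once and are not counts of genes. Repeat spots of a named accession were ordered by mean level and averaged in consecutive pairs. Agreement was measured over the 1465 pairs from accessions with exactly 2 spots, both with a value on all arrays. Their median correlation across arrays was 0.979 and the median absolute difference 0.09 on the log2 scale. Pairs with missing values, which were mostly dim, are not covered by this. A feature was tested if at least 3 arrays of each group had a value, a rule set after the missing values were seen, which left 36498 of 40930 features (3457 named, covering 3250 genes). A gene was represented by its brightest feature.

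The 3 comparisons, the tests, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. All 20 arrays entered 1 linear model with a mean per group (limma 3.58.1 in R 4.3.3: lmFit, contrasts, eBayes with an intensity trend). Tests were two-sided, p-values were adjusted over all features by Benjamini-Hochberg, and an adjusted p under 0.05 counted as a call. Adjusted p-values of single features below are from limma. Dexamethasone plus estradiol against dexamethasone is also the test of the difference between both treatment effects. In each comparison with the controls, counts, called genes and lists called by camera are also given with the 6 controls coded K alone, since treated animals had no counterpart among the M codes. For most other genes only the value with all 9 controls is given, which can differ from that with the K controls. A fit of the 9 controls tested M against K.

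Of 31 gene lists, 27 had at least 5 measured genes and were tested with camera, with its preset correlation of 0.01 between genes and again with an estimated correlation, and with fry. For these tests missing values were replaced by the mean of the gene's group. p-values were adjusted over the 27 lists. Counts "adjusted over the list alone" come from the same single-gene p-values, adjusted within the list.

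Named genes were the 10 largest rises and the 10 largest falls among called features above the 25th percentile of mean level (4.23), or, where none was called, the 3 smallest p-values in each direction; up to 4 members with the smallest p from each list described; and 18 fixed genes, of which 7 were among the named features and 11 were not analysed here. A list was described with its members if camera called it or if at least 2 members passed adjusted over the list alone, a choice made after the values were seen. The 5 largest rises and 5 largest falls named for M against K fall outside the rule and were chosen after their values were seen.

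Both treatments were set against the same 9 controls. Their correlation of log2 differences was compared with 100 simulations of unchanged groups against shared controls and was recomputed with the controls split. The same draws were refitted with limma to count shared calls, a step added after the shared calls were seen. For each count, up to 100 other splits of the same animals into groups of the same sizes were refitted. For both comparisons with the controls, 100 splits that keep the M controls as controls were added after the results were seen.

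Alternatives were quantile normalization, centring on the median, cyclic loess, leaving out dim features, a floor at the 10th percentile (2.87), 1 control code set only, the code set as a term, 2 groups only in the fit, no intensity trend, array weights, 1 feature per gene, a stricter threshold (adjusted p under 0.01, or 1.5-fold together with adjusted p under 0.05) and leaving out each animal in turn. Chosen after seeing the data were quantile normalization repeated on features with a value on all arrays, missing values set to the lowest value, leaving out the M controls together with control replicate 6, and the 6 K controls together with the repeated quantile normalization. No pair of the 190 pairs of arrays held identical values (highest correlation 0.984).

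The model was tested on simulated data of 36498 features, with changes of known size given to 67, 67 and 66 of them. The simulated noise was independent between features, with no difference between the control sets and no deviating array. The false calls below therefore do not measure those to expect in the real arrays. For dexamethasone against control the model recovered 1.49%, 19.4% and 62.1% of features changed 1.5-fold, 2-fold and 4-fold, with 3 false calls. For dexamethasone plus estradiol against control the shares were 8.96%, 34.3% and 63.6%, with 3 false calls. For dexamethasone plus estradiol against dexamethasone they were 2.99%, 8.96% and 43.9%, with 0 false calls. Tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.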

Results

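Gene expression in the anterior limb muscle of male beef cattle was compared between 9 untreated animals, 5 animals given dexamethasone and 6 given dexamethasone with estradiol. Dexamethasone, a synthetic glucocorticoid, was given in the feed at 0.75 mg per head over 43 days. Estradiol, an oestrogen, was injected into muscle 3 times at 20 mg per head. Both are steroids with growth-promoting use, as the title of the series states. Each array measured 30340 to 41306 of 44407 spots, and 36498 features were tested, 3457 of them with a gene name. The median log2 difference of all features was 0.15 for dexamethasone against control (−0.02 after cyclic loess), 0.02 for dexamethasone plus estradiol against control and −0.12 between the treatments; values called relative below have this median subtracted.

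Dexamethasone against control addressed the effect of the glucocorticoid alone. NFKBIA, the inhibitor that retains NF-kappaB in the cytoplasm, fell 3.14-fold, from a log2 intensity of 13.47 ± 0.54 (SD, n = 9) in controls to 11.81 ± 0.44 (n = 5), a log2 difference of −1.65 ± 0.24 (SE; −1.80 relative; adjusted p = 0.0217, limma). GADD45A, a growth arrest and DNA damage gene, fell 3.46-fold (−1.79 ± 0.36, −1.94 relative, adjusted p = 0.0478). SCD, the desaturase that makes monounsaturated fatty acids, rose 1.92-fold (0.94 ± 0.16, 0.79 relative, adjusted p = 0.0401). FTL, the ferritin light chain, rose 2.59-fold (1.37 ± 0.28, 1.22 relative) and CAST, the inhibitor of the calpain proteases, rose 1.75-fold (0.81 ± 0.16, 0.66 relative), both with adjusted p = 0.0478. All 5 treated animals lay on the same side of the control mean for each of these 5 genes.

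S100G, a small calcium-binding protein, passed as higher (adjusted p = 0.0473, limma) at a dim mean level of 4.55. It lay at 4.73 to 6.82 under dexamethasone. Control replicates 1 to 4, among them all M controls, lay at 2.51 to 2.61, under the 10th percentile of all values (2.87), so no fold or difference is given. PSME3IP1, a partner of a proteasome activator subunit, rose 1.52-fold (0.61 ± 0.11, 0.46 relative, adjusted p = 0.0401). SCD was measured by 12 spot pairs, of which the 3 brightest passed and the others had positive differences between 0.28 and 0.97. In all, 66 features passed, 55 higher and 11 lower, against 5516 with an unadjusted p under 0.05. Of the 66, 12 were named, 3 of them spot pairs of SCD. The others were single unnamed spots, among which a probe printed more than once could be counted more than once.

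The code numbers of the K controls, unlike those of the M controls, run on with those of the treated animals. With the 6 K controls alone, 6 features passed, all lower, so none of the 55 rises was called there. NFKBIA was the single named one (−1.72 ± 0.27, adjusted p = 0.0328). The other named changes missed the threshold there. GADD45A had −1.47 (adjusted p = 0.215), SCD 0.95 (adjusted p = 0.178), FTL 1.21 and CAST 0.74 (both adjusted p = 0.248) and PSME3IP1 0.53 (adjusted p = 0.214), similar in size to the changes with all controls. S100G had adjusted p = 0.248. The count ranged from 0 (without control replicate 1 or 3) to 177 (without control replicate 5) when 1 animal was left out, and was 0 without an intensity trend (5357 with an unadjusted p under 0.05). NFKBIA missed the threshold without control replicate 1 or 3 or dexamethasone replicate 4 or 5, with adjusted p from 0.00264 to 0.0815 over the 20 omissions. Without 1 animal, GADD45A lost its call in 13 omissions and SCD in 10 (highest adjusted p = 0.145 for both), FTL in 15 (0.152), CAST and S100G in 15 (0.145 for both) and PSME3IP1 in 11 (0.127); all 6 lost it without control replicate 1, 2, 3, 6 or 7, dexamethasone replicate 1, 4 or 5, or dexamethasone plus estradiol replicate 5.

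**Figure D1:**
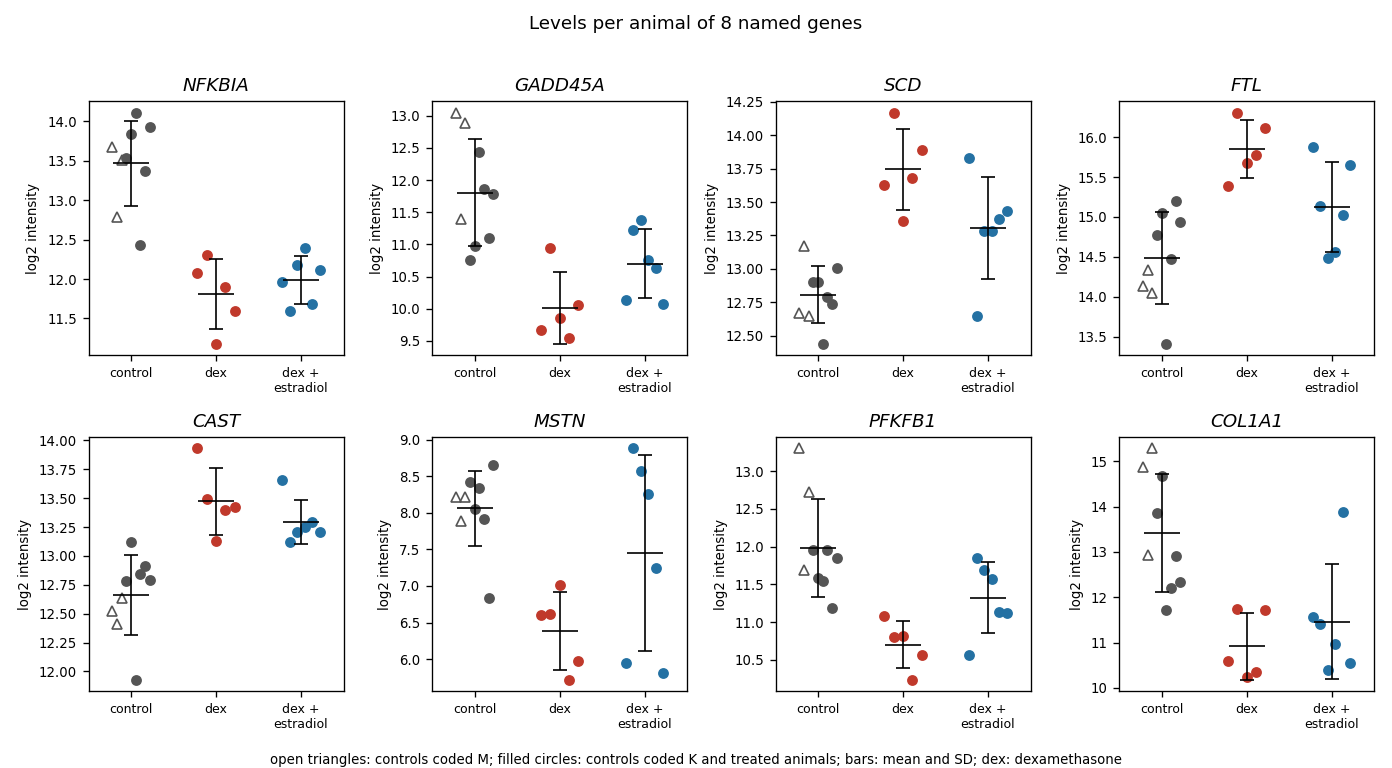
Log2 intensity per animal (vertical axes) of 8 genes in the 3 groups (horizontal axes), with open triangles for controls coded M, filled circles for all other animals, and bars for the mean and SD. NFKBIA lies at 11.18 to 12.31 in the dexamethasone group and at 12.43 to 14.11 in the controls; MSTN, PFKFB1 and COL1A1 are shown although they did not pass over all features.

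Among 8 measured glucocorticoid target genes, 0 rose, 2 fell (NFKBIA and GADD45A) and 6 did not pass; adjusted over the list alone, 1 rose and 3 fell. GLUL, glutamine synthetase, stood at 0.52 ± 0.21 (adjusted p = 0.248) and PIK3R1, a regulatory subunit of PI3-kinase, at −0.81 ± 0.29 (adjusted p = 0.187). NFKBIA and GLUL are known as genes that glucocorticoids induce in many tissues. Camera placed the list lower than other genes (adjusted p = 0.0208; adjusted p = 0.613 with an estimated correlation; adjusted p = 0.0122 with K controls).

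The 9 genes of glycolysis and glycogen use were lower as a list (median −0.35, camera adjusted p = 0.000555; adjusted p = 0.613 with an estimated correlation; adjusted p = 0.00227 with K controls). Over all features 0 rose, 0 fell and 9 did not pass; adjusted over the list alone, 3 fell. These were PFKFB1, an enzyme that sets the level of fructose 2,6-bisphosphate, at −1.27 ± 0.28 (adjusted p = 0.0603), LDHA, lactate dehydrogenase, at −0.69 ± 0.18 (adjusted p = 0.0829), and PYGM, muscle glycogen phosphorylase, at −0.78 ± 0.22 (adjusted p = 0.0961). GAPDH, measured by 6 bright spot pairs, had −0.30 ± 0.13 on the brightest (adjusted p = 0.288) and −0.65 to −0.74 on the 3 dimmer ones (adjusted p from 0.11 to 0.126).

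Cytosolic ribosomal protein genes were higher as a list. Of 42 genes 39 had a positive difference, with a median of 0.24 where all named genes had 0.134 (camera adjusted p = 0.00343; adjusted p = 0.879 with an estimated correlation; adjusted p = 7.59e-05 with K controls). None passed singly, over all features or adjusted over the list alone, and RPL10A (0.47 ± 0.18) and RPS14 (0.33 ± 0.12) ran opposite to RPS27L (−0.84 ± 0.25). The 53 genes of oxidative phosphorylation had a median of 0.00 and a mean of −0.04, below the other genes (camera down, adjusted p = 0.00985; adjusted p = 0.879 with an estimated correlation; adjusted p = 0.000584 with K controls). With 27 differences above 0 and 26 below, the list itself did not fall. Its place rests in part on the upward shift of the other genes. The median of all features was −0.018 after cyclic loess, under which the lists were not tested. Over all features 0 of the 53 rose or fell, and adjusted over the list alone 1 fell, NDUFS3, a complex I subunit (−0.53 ± 0.13, adjusted p = 0.0755). The list lost its call without control replicate 7 or 9 or dexamethasone replicate 2 (highest adjusted p = 0.228).

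Slow fibre genes were higher as a list of 6, all with positive differences (median 0.65, camera adjusted p = 0.0428; adjusted p = 0.879 with an estimated correlation). The list was not called with K controls (median 0.27, adjusted p = 0.311), and 7 of the 20 omissions of 1 animal ended the call: control replicates 1, 2, 3 and 6, dexamethasone replicates 3 and 4, and dexamethasone plus estradiol replicate 1 (highest adjusted p = 0.215). Its members MYOZ2, a sarcomere Z-line protein (1.53 ± 0.60), TNNT1, slow troponin T (0.68 ± 0.27), TPM3, slow tropomyosin (0.83 ± 0.35) and CSRP3 (0.62 ± 0.32) did not pass over all features or adjusted over the list alone. MYH7, the slow myosin heavy chain, had 0.07 ± 0.11 and MYH1, a fast one, −0.33 ± 0.21 (−0.08 on its other spot pair).

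Leukocyte markers were lower as a list of 14, 10 with negative differences (median −0.52, camera adjusted p = 0.0208; adjusted p = 0.879 with an estimated correlation; adjusted p = 0.0192 with K controls). None passed singly, over all features or adjusted over the list alone; CD8A, a T cell surface protein, had −1.15 ± 0.46 and PTPRC, the common leukocyte antigen, −0.63 ± 0.42. The call was lost without control replicate 1 or 8 or dexamethasone replicate 1, 3 or 4 (highest adjusted p = 0.21). The 9 cell cycle genes were lower as a list (median −0.28, camera adjusted p = 0.00343; adjusted p = 0.797 with an estimated correlation), but not with K controls (adjusted p = 0.149). None passed, and the members with the smallest p, CCNB2 and MCM3, were dim, at mean levels of 4.29 and 3.45. In dexamethasone replicates 1, 3 and 4 they lay at 2.61 to 2.77 and 2.44 to 2.8. These values are under the 10th percentile of all values (2.87), so no differences are given. The 7 calls of 27 lists all rested on the preset correlation: 0 lists passed with an estimated correlation (smallest adjusted p = 0.613) and 0 with fry (smallest adjusted p = 0.189).

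Among the fixed genes, MSTN, which encodes myostatin, the secreted inhibitor of muscle growth, did not pass over all features. Its level was 6.39 ± 0.53 (SD, n = 5) under dexamethasone and 8.06 ± 0.52 (n = 9) in controls, a difference of −1.68 ± 0.46 (adjusted p = 0.0937; −1.65 with K controls, adjusted p = 0.361). NR3C1, the glucocorticoid receptor, had −0.43 ± 0.57 with all controls and 0.17 ± 0.55 with K controls (adjusted p = 0.778 and 0.936). IGF1, a muscle growth factor, had −0.21 ± 0.46 and PGR, the progesterone receptor, 0.36 ± 0.49. PGR was dim, with controls at 2.45 to 5.77, so its value says little about a change.

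**Figure D2:**
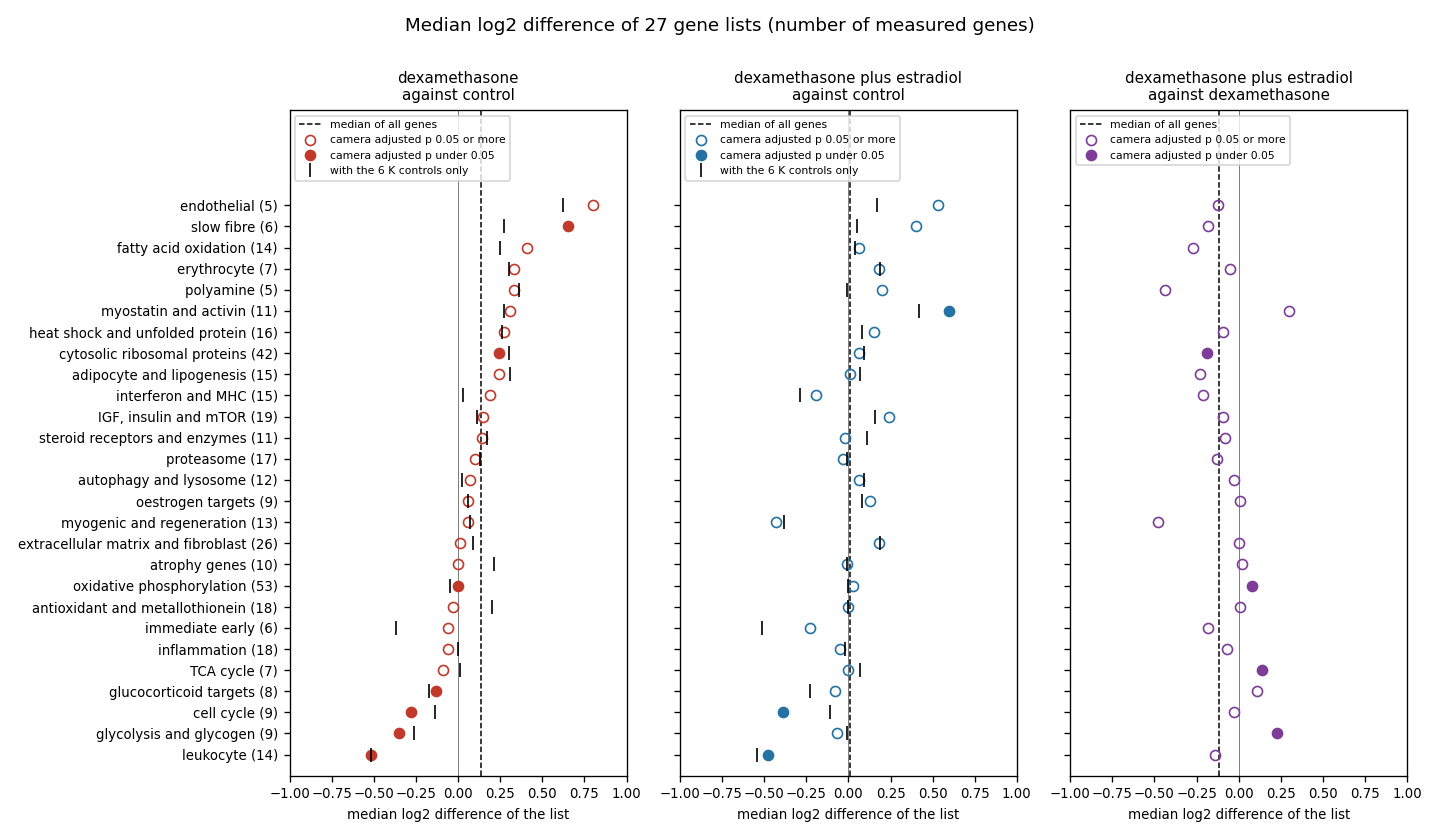
Median log2 difference (horizontal axes) of 27 gene lists (vertical axis, with the number of genes) in the 3 comparisons; filled points have a camera adjusted p under 0.05 with the preset correlation, short bars give the median with K controls only, and the dashed line is the median of all genes. The slow fibre median moves from 0.65 to 0.27 with K controls, while the leukocyte median is −0.52 with either set.

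Dexamethasone plus estradiol against control addressed the combined treatment. NFKBIA fell 2.79-fold, to 11.99 ± 0.31 (SD, n = 6) from 13.47 ± 0.54 (n = 9), and all 6 animals lay below the control mean (−1.48 ± 0.23, adjusted p = 0.0234, limma). It was the single named feature among 6 that passed, 3 higher and 3 lower, against 3743 with an unadjusted p under 0.05. GADD45A, called under dexamethasone alone, had −1.10 ± 0.34 (adjusted p = 0.324). With K controls alone 4 other features passed, all lower, and NFKBIA missed the threshold (−1.55 ± 0.25, adjusted p = 0.0539). The count was 0 without control replicate 3 or dexamethasone plus estradiol replicate 3, and NFKBIA was lost without control replicate 1, 3, 5 or 8 or dexamethasone plus estradiol replicate 2, 3 or 5 (highest adjusted p = 0.0855).

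Of the 27 lists, 3 were called. The 14 leukocyte markers were lower (median −0.48, 12 with negative differences, camera adjusted p = 0.0145; adjusted p = 0.921 with an estimated correlation; adjusted p = 0.0119 with K controls). Of these 0 passed singly, over all features or adjusted over the list alone; PTPRC had −0.80 ± 0.40 and CORO1A, a leukocyte actin-binding protein, −1.08 ± 0.57. The call was lost without control replicate 1 or dexamethasone plus estradiol replicate 4 (highest adjusted p = 0.0739). The 11 genes of myostatin and activin signalling were higher (median 0.60, camera adjusted p = 0.0145; adjusted p = 0.872 with an estimated correlation; adjusted p = 0.0515 with K controls). Of these 0 passed over all features or adjusted over the list alone; INHBA, an activin subunit, had 0.66 ± 0.33, and ID2 and ID3, inhibitors of differentiation factors, 0.87 ± 0.35 and 1.03 ± 0.43. The member with the smallest p, TGFBR1, a receptor kinase, was dim, with control replicates 2, 3 and 4 at 2.59 to 2.82, under the 10th percentile of all values (2.87), so no difference is given. The ligand MSTN itself had −0.61 ± 0.43 (adjusted p = 0.658).

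All 9 cell cycle genes had negative differences (median −0.39, camera adjusted p = 0.0145; adjusted p = 0.872 with an estimated correlation). The list was not called with K controls (adjusted p = 0.318) or without control replicate 1 (adjusted p = 0.051). Over all features 0 of the 9 passed. Adjusted over the list alone 1 fell, CCNB2, a mitotic cyclin, at a dim mean level of 4.29. In dexamethasone plus estradiol replicates 2, 4 and 6 it lay at 2.5 to 2.67, under the 10th percentile (2.87), so no difference is given. Neither an estimated correlation (smallest adjusted p = 0.872) nor fry (smallest adjusted p = 0.511) called any list in this comparison. Glucocorticoid targets gave camera adjusted p = 0.0779 (adjusted p = 0.872 with an estimated correlation), with 1 of 8 lower over all features and, adjusted over the list alone, 1 higher (ZBTB16, a zinc finger repressor, 0.71 ± 0.25) and 3 lower.

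Dexamethasone plus estradiol against dexamethasone addressed what the added estradiol changed. No feature passed: 0 of 36498 with limma (smallest adjusted p = 0.671), with 1566 at an unadjusted p under 0.05. It was 0 under every other scaling, filter and weighting, and 1 without dexamethasone replicate 5 or dexamethasone plus estradiol replicate 5. The genes with the smallest p, none past the threshold, were lower for BRIX1, a ribosome biogenesis factor (−0.75 ± 0.21, −0.62 relative), ZNHIT2 (−0.73 ± 0.23, −0.61 relative) and GLUL (−0.67 ± 0.23, −0.55 relative), and higher for BMPR1A, a BMP receptor (0.51 ± 0.19, 0.63 relative; −0.70 on its other, dim feature), PRKAR2B, a regulatory subunit of protein kinase A (1.40 ± 0.52, 1.52 relative), and PYGM (0.60 ± 0.23, 0.72 relative), each with adjusted p = 0.982. PRKAR2B was dim, at 3.12 to 5.23 under dexamethasone, and had no value in dexamethasone plus estradiol replicate 6. MSTN had 1.06 ± 0.50 (1.19 relative, adjusted p = 0.982), and its 6 values under the combined treatment spread from 5.81 to 8.88.

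Of the 27 lists, 4 were called with the preset correlation. Oxidative phosphorylation (median 0.08, camera adjusted p = 6.65e-05), glycolysis and glycogen (median 0.23, adjusted p = 0.000445) and the TCA cycle (median 0.14, adjusted p = 0.0206) were higher than other genes. The other genes were shifted downward here. The median of all features was −0.123, and 0.006 after cyclic loess, under which the lists were not tested. Cytosolic ribosomal proteins were lower (median −0.19 where all named genes had −0.118, 39 of 42 below 0, camera adjusted p = 0.000598). The same dexamethasone animals enter dexamethasone against control, so lists that turn between both comparisons are not independent results. All 4 lists had adjusted p = 0.882 with an estimated correlation, and fry called 0 (smallest adjusted p = 0.878). In these lists 0 genes rose or fell over all features or adjusted over the list alone. Their members with the smallest p were NDUFS3 (0.33 ± 0.14), PYGM and PFKFB1 (0.62 ± 0.31), PDHA1, a pyruvate dehydrogenase subunit (0.66 ± 0.41), and RPS4X (−0.58 ± 0.27). The TCA cycle lost its call without dexamethasone replicate 5 or dexamethasone plus estradiol replicate 2 or 3 (highest adjusted p = 0.116).

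The log2 differences of both treatments against control correlated across features with r = 0.669, and 72% had the same sign; features are not independent replicates. Because both share the 9 controls, unchanged groups against shared controls gave a mean r of 0.374 (SD 0.13, highest 0.713), and 1 of 100 simulations reached the observed value. The covariance was 0.201 against a simulated 0.0657, a difference of 0.135. The simulations spread the M controls and control replicate 6 over all groups, whereas in the data they all lie in the shared controls. A difference of these animals from the others can raise the observed correlation and covariance. The simulations therefore cannot tell a shared response to treatment from such a difference. With the controls split, r was 0.377 and 0.42 (covariance 0.141 and 0.15). With the K controls split, r was 0.213 and 0.199 and the covariance was lower, at 0.0703 and 0.0643. Shared calls were 1 higher and 1 lower, NFKBIA. Independent lists would share 0.0045 and 9e-04, a value that leaves out the shared controls. Unchanged groups against shared controls had 0 shared calls in 100 simulations, of which only 1 had calls in both comparisons, so neither number measures how far the controls alone make calls coincide.

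The 9 controls themselves differed by code. OXT, which encodes the oxytocin precursor, was 11.1-fold higher in the 3 M controls, at 12.05 ± 0.77 (SD, n = 3) against 8.57 ± 0.63 (n = 6) in the K controls (3.48 ± 0.43 (SE), adjusted p = 0.00935, limma). GPNMB, a transmembrane glycoprotein of macrophages and other cells, was 13.3-fold higher in the M controls (3.73 ± 0.71, adjusted p = 0.0358). TREM1 and TLR6, receptors of innate immune cells, were 5.76-fold and 3.3-fold higher, and CEBPA, a transcription factor of adipocytes and myeloid cells, 3.66-fold higher. Lower in the M controls were CCL21, a lymphoid chemokine (6.81-fold), CFLAR, an inhibitor of caspase activation, GFAP, a glial filament protein, and HBB, beta-globin. CFLAR, GFAP and HBB were near the lowest levels in the M controls (down to 3.26, 2.69 and 2.88), GFAP and HBB with values in 5 and 4 K controls, so no fold or difference is given for them. The MHC class II gene BOLA-DQA2 passed as well (adjusted p = 0.0397), but lay at 2.66 and 3.26 in control replicates 1 and 3 and at 10.42 in control replicate 2, near the lowest K control (11.42).

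In all, 547 of 35768 features passed between the control sets, 423 higher and 124 lower in the M controls. Of the 66 features called for dexamethasone, 0 were among them. A feature that differs between the sets varies more within the pooled controls and is less easily called there, so this decides nothing about the M controls. Of the 3706 features called for dexamethasone against the M controls alone, 470 were among the 547, and both tests hold the same M controls. The count for M against K ranged from 60 (without control replicate 3) to 2175 (without control replicate 6, 976 higher and 1199 lower, so the balance of directions turned), with 84 without control replicate 1, 244 without control replicate 2, 307, 342, 302 and 259 without control replicates 5, 7, 8 and 9. OXT lost its call without control replicate 1 or 3 (highest adjusted p = 0.0559); the other named genes lost theirs in 6 to 8 of 9 omissions. Camera called interferon and MHC genes (median −0.88, adjusted p = 0.00176) and slow fibre genes (median −0.95, adjusted p = 0.0219) lower and cell cycle (median 0.89, adjusted p = 0.00194), glycolysis and glycogen (median 0.27, adjusted p = 0.00762) and ribosomal protein genes (median 0.15, adjusted p = 0.0472) higher in the M controls. With an estimated correlation 0 were called (smallest adjusted p = 0.281).

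**Figure D3:**
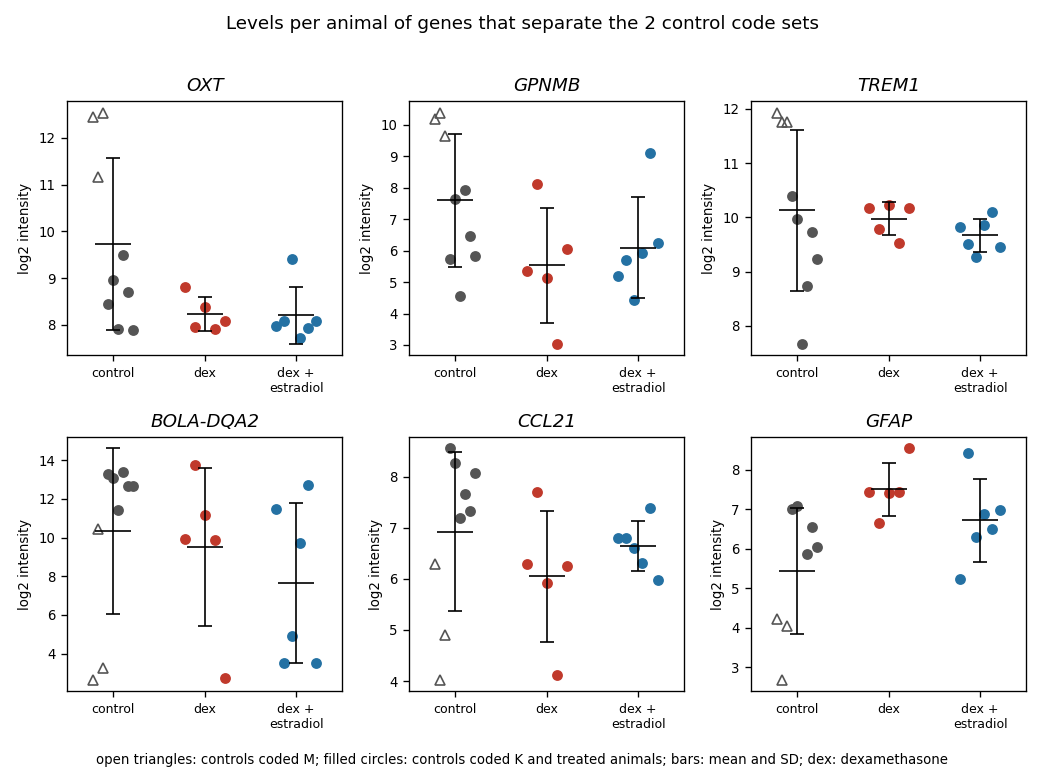
Log2 intensity per animal (vertical axes) of 6 genes that differed between control code sets, in the 3 treatment groups (horizontal axes); open triangles are controls coded M, filled circles all other animals, bars the mean and SD. OXT lies at 11.16 to 12.54 in the M controls and at 7.72 to 9.5 in all other animals, while BOLA-DQA2 also spans 2.74 to 13.74 among treated animals.

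Principal components were computed over 19273 features with a value on all arrays. Control replicate 6 lay apart on the first component (35.1% of the variance), at −167.6, and the M controls on the second (18.5%), at 74.3 to 87.9 against −37.6 to 24.5 for all other arrays. With quantile normalization repeated on these features the order turned: the M controls lay apart on the first component (28.1%), at 76.5 to 85.2 with control replicate 6 next at 36.8. On the second (13.9%) control replicate 6 lay at −80.5, near dexamethasone plus estradiol replicate 3 (−63.9). The median correlation between arrays was 0.952 between M and K controls, 0.939 between M controls and treated animals and, without control replicate 6, 0.971 between K controls and treated animals.

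**Figure D4:**
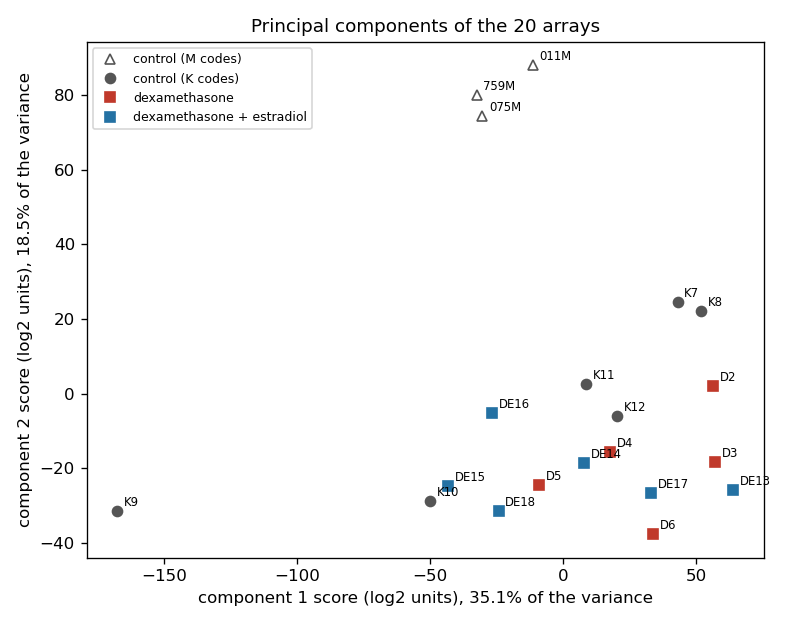
Scores of the 20 arrays on the first (horizontal axis) and second (vertical axis) principal component of log2 intensity, marked by group and control code; K9 is control replicate 6. The 3 M controls lie at 74.3 to 87.9 on the second component.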

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

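Of the tests in this part, the comparison of array quality and the splits that keep the M controls as controls were chosen after the result was seen, and so were both tests of how the dexamethasone calls depend on the M controls, whose bounds were also set after their values were seen. The 303 groups of 4 to 10 animals examined here hold the same 20 animals and are not independent, so their share is no test against chance. In 26 of the 303 (8.58%) the highest or lowest value stood apart from the rest, where independent groups would give about 1 in 20 by chance.

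Many of these were low values of control replicate 6, whose array had the most spots without a value (31.68%): AMD1 5.72, ATP5MC3 15.1, CCN2 9.79, GABARAPL2 13.69, GPX3 5.1, MDH2 12.47, NDUFA1 13.95, RPL5 15.37, RPS14 17.06 and a score of −167.6 on the first principal component. MSTN was lowest in control replicate 8 (6.84, next 7.89). In dexamethasone replicate 2, CCNB1 (4.9, next 2.81) and CCNB2 (6.28, next 2.94) stood high, and LAMP2 (12.03) and NDUFA1 (14.07) low. Dexamethasone replicate 4 was low for GPI (15.02), PDHA1 (6.57) and TNNT1 (17.19). Dexamethasone replicate 1 was low for P4HA2 (11.77) and high for ZBTB16 (11.94), and dexamethasone replicate 5 was high for RPS14 (18.1). Under the combined treatment, replicate 1 was high for CAST (13.66), replicate 5 high for COL1A1 (13.88) and COL1A2 (12.57), replicate 4 low for TGFBR1 (3.4) and replicate 3 high for OXT (9.41).

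Control replicate 6 lay 0.912 from the mean of the other K controls (median absolute log2 distance), where each other K control lay 0.265 to 0.425 from the mean of the rest. Its equal quantiles were imposed over fewer measured spots. With quantile normalization repeated on features with a value on all arrays, the distance fell by 51.7% to 0.44, while the other K controls came to 0.213 to 0.265. Scaling over unequal numbers of spots may thus account for part of the difference, but the array remained the farthest. No biological explanation was tested.

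The M and K controls differed in 547 features. Of the 84 splits of the 9 controls, 1, the real one, gave as many (highest other 85). Chance is thus an unlikely reason for the count. As 1 of 84 is the smallest share these splits can give, it cannot be firmly excluded. A difference in array quality stays open: 0 of the 3 M arrays (13.02% to 16.5% of spots without a value) lay outside the range of the K arrays (7.19% to 31.68%), but that range is wide, and RNA quality, labelling and hybridization were not measured here. Another makeup of cell types cannot be told apart: among 5 lists of markers of other cell types, medians ran from −0.53 to 0.21 and the smallest adjusted p was 0.977 with an estimated correlation (0.248 with the preset one), so no list was called, while the medians were not all near 0. A batch, another origin or another breed behind the codes stays open, as the labels do not say what they mean. The M codes lie outside the run of numbers shared by the K controls and the treated animals, which does not tell these apart.

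For dexamethasone, 3 of 100 splits, the real one among them, gave at least the real count of 66. The others gave 2501, with all 3 M controls in one group, and 354, with none. With the M controls kept as controls in every split, 2 of 100 gave at least 66, the real one and 1 with 876. Few splits reached the real count, so chance is an unlikely reason for it but cannot be firmly excluded. Random splits with counts far above 66 show that a high count is not particular to the treatment. Why they arise was not tested. With K controls alone the median change of the 66 features was 91.8% of its value (1.49 to 1.36). These features were chosen by a fit that holds the same 6 K controls, so that share decides nothing about the M controls. Leaving out 3 K controls in place of the M controls gave a median of 231 features, but 0 to 1640 over 20 choices, 5 of them at most the 6 found without the M controls, and it raises the share of M controls as well. Fewer controls as the reason for the fall to 6 cannot be told apart from a difference of the M controls, and why the count depends on them stays open. For dexamethasone plus estradiol 5 of 100 splits gave at least the real 6 (highest other 31), and 7 of 100 with the M controls kept as controls (highest other 25), so chance cannot be excluded. Between the treatments the real count was 0, which each of the 100 splits must reach (100 of 100, highest other 14), so the splits decide nothing there.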

How the results depend on the processing

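Alternatives chosen after seeing the data are the repeated quantile normalization, missing values at the lowest value, and those leaving out control replicate 6 or combining 2 choices. No called result changed sign, but 28 values of uncalled genes did, such as NR3C1 for dexamethasone (−0.43, 0.17 with K controls), IGF1 (−0.21, 0.3 with missing values at the lowest value) and CSRP3 (0.62, −0.06 without M and control replicate 6). The cause of each change below was not tested unless stated.

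For dexamethasone (66 features), the count was 396 with quantile normalization, 545 with median centring, 351 with cyclic loess (238 higher, 113 lower; 67.8% higher against 83.3%), 288 without the dimmest features (27373 left), 329 without more of them (18249 left), 151 with array weights, and 748 with quantile normalization repeated on features with a value on all arrays. It was 33 with a floor, 32 with missing values at the lowest value, 0 without an intensity trend (5357 at an unadjusted p under 0.05) and 0 at adjusted p under 0.01. By controls it was 6 with K, 7 with the code set as a term, 3706 with M, 4 without M and control replicate 6, and 21 with K and repeated quantile normalization. The share higher, 83.3% with all controls, was 0% with K and without M and control replicate 6, and 14.3% with the term. With 1 feature per gene, 28 of 3250 named genes passed (20 higher, 8 lower), where 12 named features passed among all 36498, 10 of them shared. Of the 66, 66 were shared under quantile normalization and under median centring, 64 with M controls, 49 under repeated quantile normalization and 1 with K controls.

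For dexamethasone plus estradiol (6 features), the count was 17 with median centring, 13 of them higher (76.5% against 50%), 3598 with M controls, 2 with 2 groups in the fit, 10 with array weights, 2 with 1 feature per gene (1 of the 6 was named), 45 with repeated quantile normalization, 3 with missing values at the lowest value and 0 at adjusted p under 0.01. With cyclic loess 8 passed (12.5% higher), and with a floor 5 (20%). With the code set as a term 9 passed, and without M and control replicate 6 it was 5, with 0 higher in both.

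Leaving out 1 animal gave 0 to 177 for dexamethasone; within 1.5 times of 66 lay only 89, without dexamethasone plus estradiol replicate 3. It was 4, 34, 4, 2, 156 and 170 without control replicates 2, 4, 6, 7, 8 and 9, 18, 27, 13, 2 and 1 without dexamethasone replicates 1 to 5, and 138, 28, 35, 3 and 37 without dexamethasone plus estradiol replicates 1, 2, 4, 5 and 6. For the combined treatment the range was 0 to 8, with 2, 3, 3 and 2 without control replicates 1, 5, 7 and 8, and between treatments 0 to 1. M against K gave 60 to 2175, 888 with quantile normalization and 2052 with its repeat; the share higher in M, 77.3%, was 44.9% without control replicate 6 and 54.1% with the repeat.

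The correlation of both treatments ranged from 0.573 to 0.877, the latter with M controls; leaving out 1 animal gave 0.589 to 0.708. Of the called lists (7, 3 and 4), 0 held with an estimated correlation and 0 with fry in each comparison. The combined treatment had 1 without the dimmest features and 1 with repeated quantile normalization. Without 1 animal the lists numbered 5 to 8, 1 to 5 (1 without control replicate 1, 5 without dexamethasone plus estradiol replicate 2) and 3 to 6. Of 4282 alternative values of 121 single results, 4026 kept their direction and side of the threshold, 136 fell short of it, 92 passed it and 28 changed sign. Most of the 121 were not called and kept their side by staying uncalled. The 4026 therefore do not measure how stable the calls were, and only called genes could fall short. Called genes lost their call in 4 to 15 of the 20 omissions of 1 animal. No paired analysis was possible because replicate numbers only name animals. Signal over background limits dim features: 34.4% of cells were empty below a mean log2 of 4.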

Other observations

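The groups described here were chosen after the values were seen, by members past the threshold adjusted over the list alone. Further gene groups differed in single members under dexamethasone; of their genes only CAST passed over all features. In fatty acid oxidation (14 genes), adjusted over the list alone 2 rose and 1 fell. UCP3, a mitochondrial uncoupling protein, had −2.59 ± 0.70 (adjusted p = 0.0906; −1.83 with K controls), CPT1B, the muscle enzyme that admits fatty acids to mitochondria, 0.88 ± 0.26, and PPARA, a fatty acid-activated transcription factor, 1.52 ± 0.52; FABP3, the muscle fatty acid carrier (1.66 ± 0.62), did not pass adjusted over the list alone. Among 18 antioxidant and metallothionein genes 2 rose and 1 fell adjusted over the list alone: GPX3, the secreted glutathione peroxidase, had 1.87 ± 0.50 (adjusted p = 0.0885), GSS, glutathione synthetase, 0.77 ± 0.24, and GPX4, the lipid peroxidase, −0.96 ± 0.22 (adjusted p = 0.0659). Of 11 myostatin and activin genes 3 rose and 1 fell adjusted over the list alone. MSTN was the fall, and ID2 (1.24 ± 0.37), INHBA (1.03 ± 0.35) and FST, follistatin, a secreted antagonist of myostatin and activin (1.68 ± 0.58), were the rises. Among 26 extracellular matrix genes 1 rose and 1 fell adjusted over the list alone: P4HA2, a collagen prolyl hydroxylase, had 0.87 ± 0.21 (adjusted p = 0.0671) and COL1A1, a type I collagen chain, −2.50 ± 0.60 (adjusted p = 0.0718; −2.02 with K controls). Camera called none of these 4 lists (adjusted p = 0.334, 0.491, 0.491 and 0.323; 0.879 each with an estimated correlation). The antioxidant list had a median of −0.03 and a mean of 0.12 with camera down, the matrix list a median of 0.01 and a mean of −0.05.

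ARG2, a mitochondrial arginase, had the largest difference among the genes named for dexamethasone (4.42 ± 1.10, adjusted p = 0.0771; 2.98 ± 0.88 with K controls, adjusted p = 0.309). Its levels were 5.52 to 8.13 in the M controls, 6.66 in control replicate 6, 10.39 to 12.62 in the other K controls and 13.21 to 14.61 under dexamethasone. Of 5 polyamine genes 2 rose and 1 fell adjusted over the list alone; AMD1, which makes the aminopropyl donor, had 1.18 ± 0.48 and ODC1, which makes putrescine, −0.74 ± 0.30 (camera adjusted p = 0.334; adjusted p = 0.879 with an estimated correlation). Of 12 autophagy and lysosome genes 2 rose and 1 fell adjusted over the list alone: GABARAPL2, which acts in autophagosome formation, had 0.60 ± 0.19 (adjusted p = 0.144), BNIP3L, a mitophagy receptor, 0.92 ± 0.32 (adjusted p = 0.174), and LAMP2, a lysosomal membrane protein, −0.61 ± 0.18 (adjusted p = 0.12). The other, also bright feature of LAMP2 had −0.17 (adjusted p = 0.775), so the fall rests on 1 of 2 features. Of 10 atrophy genes 1 rose over all features, CAST, and adjusted over the list alone 1 rose and 1 fell (MSTN); the list had a median of 0.00 and a mean of −0.14. Camera called neither list (adjusted p = 0.968 and 0.491; adjusted p = 0.98 and 0.879 with an estimated correlation).

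Under the combined treatment 1 rose and 1 fell adjusted over the list alone among 18 antioxidant genes, HMOX1, heme oxygenase (1.15 ± 0.33, adjusted p = 0.277), and GPX4 (−0.79 ± 0.21, adjusted p = 0.25). Among 19 IGF, insulin and mTOR genes they were IGF2R, the receptor that clears IGF2 (0.41 ± 0.12, adjusted p = 0.285), and PIK3R1 (−0.91 ± 0.27, adjusted p = 0.307), and GRB14, an inhibitor of insulin receptor signalling, had 1.36 ± 0.52. Camera called neither list (adjusted p = 0.917 and 0.18; adjusted p = 0.974 for both with an estimated correlation); the antioxidant list had a median of 0.00 and a mean of 0.08 with camera down. With K controls, interferon and MHC genes were called lower in both treatments (adjusted p = 0.0157 and 0.00132; adjusted p = 0.956 and 0.937 with an estimated correlation), but not with all 9 controls (adjusted p = 0.358 and 0.18).

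Under the combined treatment MSTN and UCP3 were both low in replicates 1 and 6 (MSTN 5.94 and 5.81, UCP3 9.08 and 9.18) and both higher in replicates 2, 3 and 4 (MSTN 8.88, 8.57 and 8.26, UCP3 11.79, 11.66 and 11.05), with replicate 5 between them (7.24 and 10.21). This was noticed in the values and was not tested.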
